A study of Arabidopsis thaliana with 8 samples.

How the data were processed

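Whole seedlings of 2 Arabidopsis thaliana hybrids were profiled by RNA sequencing. The Col hybrid is C24 crossed with Col, and the pif4 hybrid is C24 crossed with pif4-101, a mutant allele of PIF4 in the Col background. PIF4 encodes a basic helix-loop-helix transcription factor that acts in growth under warmth and shade. Per the labels, seedlings germinated at 22 °C under short days, were then kept at 22 °C or 27 °C, and were pooled and collected at ZT0, the time of lights on, 4 or 7 days after sowing. This gives 8 conditions with 1 library each, so no condition had a replicate. Pooling averages over seedlings, and the spread between pools of the same condition is unknown.

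The authors deposited raw read counts per gene, whole numbers that were not normalised. The authors' processing notes name FastQC 0.11.5, HISAT2, Picard, StringTie 1.3.5 and HTSeq 0.6.1p1 with the genome build TAIR10, without roles, order or settings. Strand setting, read filters and handling of duplicates are not stated. Per the labels, both a stranded and an unstranded library kit were used, without saying which library had which. Counts of genes that overlap a neighbour on the opposite strand are therefore uncertain, as are those of close paralogs such as the RBCS, LHCB, extensin and ribosomal protein genes, whose reads may be shared. Reads came from hybrids, and how reads with C24 alleles mapped to the Col reference is unknown. Gene symbols were taken from the TAIR10.1 annotation, in which 32835 of the 33602 counted loci were found; 19 of the 453 listed loci carry another symbol there and are named by it (UNE10 for PIF8, HSP70 for HSP70-4, PCB2 for DVR). Coordinates were used only to find genes that overlap a neighbouring gene in that annotation.

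Genes were kept when their library-scaled counts (CPM, edgeR) reached that of 10 counts in the library of median size, 0.876 CPM, in 4 or more of the 8 libraries, which left 19829 genes. Counts were scaled by TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F-test, R 4.3.3), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Temperature (27 °C against 22 °C), genotype (pif4 hybrid against Col hybrid) and age (day 7 against day 4) were each tested with the other factors as covariates. Each factor thus compared 4 libraries with 4, as 4 matched pairs with 4 residual degrees of freedom, and any real interaction adds to the spread. The genotype-by-temperature, age-by-temperature and genotype-by-age terms were each tested in a model with that term and 3 residual degrees of freedom. The first of these also gave the temperature effect within each hybrid. All p-values measure only the spread between these 8 samples. Changes are log2 fold changes with an approximate standard error (SE). The SE was derived as the size of the change divided by the square root of its edgeR F statistic. An n of 4 matched pairs applies to each main effect.

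Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, adjusted over the 26 lists. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move, on balance, one way. The lists were PIF family, PIF-induced shade and elongation genes, auxin synthesis, auxin early response, circadian clock, gibberellin synthesis and signalling, brassinosteroid synthesis, ethylene synthesis and signalling, heat shock, cold response, abscisic acid response, salicylic acid defence, jasmonate synthesis and response, glucosinolate synthesis, light harvesting and photosystems, chlorophyll synthesis, flavonoid and anthocyanin synthesis, cell wall loosening, cell cycle, flowering time, dark and sugar starvation, stomatal lineage, trichome, seed storage and reserve use, root, and cytosolic ribosomal proteins. Some genes stand in more than 1 list, such as XTH15, IAA19, IAA29, YUC8 and CYP79B2. The ribosomal list was drawn by a rule on the reference text, which found 57 genes, a part of the known set. It also took in some genes that are not cytosolic ribosomal proteins, such as the plastid protein gene RPL9. A form of the list limited by text was added after seeing the data.

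Named genes were chosen by a fixed rule. For the main effects these were the 6 genes that rose and the 6 that fell most among those past the threshold with 1 sign in all 4 pairs and a mean of at least 5 CPM, and up to 3 genes with the smallest p from each list. For interactions and effects within a hybrid these were the 4 highest and the 4 lowest past the threshold with a mean of at least 5 CPM, or, where none passed, the 3 with the smallest p. PIF4, its family, CCA1, LHY, IAA19, IAA29, YUC8, ATHB2, FLC and HSP70-4 were added for the main effects and the genotype-by-temperature term. They are named only where the text uses them, and most are not given for age. The samples, tests, lists, naming rule and most alternatives were chosen before the data were examined.

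The design was tested on simulated data with 200 changed genes per comparison. Each gene was drawn independently, with the same dispersion for every gene and no effect other than the planted one. Changed genes had a mean of at least 5 CPM. In the real data interactions and differences between libraries add to the spread, so the shares recovered need not hold there. For main effects, 68.0% to 76.0% of 2-fold and 100% of 4-fold changes were recovered, with at most 6 false calls. For interactions 1.0% to 6.0% of 2-fold and 63.0% to 73.0% of 4-fold changes were recovered, so small interactions could not be seen. On the simulated temperature counts, where only the 200 genes drawn without regard to the lists changed, camera called 0 of 26 lists. It called a list of 18 genes that was then raised 2-fold. Because simulated genes did not vary together, this run cannot check the preset correlation.

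Alternatives were RLE or upper-quartile scaling, no filter or a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, no organelle genes, no covariates, all pairwise interactions, a 2-fold minimum, each age or hybrid alone, and each library left out in turn. Added after seeing the data were the log2 library total as a covariate, offsets that remove each library's trend with read density, and thinning of all libraries to the smallest total. The 95% intervals for PIF4 are exact binomial (Clopper-Pearson) and cover counting error only.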

Results

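Transcript levels were measured by RNA sequencing in whole seedlings of the Col hybrid and the pif4 hybrid, grown at 22 °C or 27 °C and collected on day 4 or day 7. Each of the 8 conditions had 1 library, so each factor was compared across 4 matched pairs of libraries. Total counts differed widely. In the Col hybrid they were 1664128 at 22 °C and 9128810 at 27 °C on day 4, and 11711681 and 25440561 on day 7. In the pif4 hybrid they were 8880735 and 20898400 on day 4, and 17884174 and 11125696 on day 7. A gene with 0 counts could still have had up to 2.14 TMM-scaled CPM, the level of 3 counts, in the shallowest library and up to 0.106 in the deepest. Chloroplast genes took 0.659% to 1.21% of the counts, and mitochondrial genes 0.0420% to 0.0723%. The first principal component, 47.7% of the variance, separated the ages, and the second, 28.8%, separated the temperatures.

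PIF4 (AT2G43010), the gene that the pif4 hybrid targets, was read in all 8 libraries and was higher at 27 °C in every pair. In the Col hybrid PIF4 was at 97.3 CPM (136 counts) at 22 °C and 176.4 CPM (1624 counts) at 27 °C on day 4, and at 72.8 CPM and 187.2 CPM on day 7. In the pif4 hybrid it was at 79.5 CPM and 186.3 CPM on day 4, and at 62.5 CPM and 157.3 CPM on day 7. Before TMM scaling, the 95% interval of the shallowest library was 68.6 to 96.7 CPM, and that of the pif4 hybrid at 22 °C on day 4 was 71.3 to 82.9 CPM. PIF4 rose with temperature by a log2 fold change of 1.21 (SE 0.11, adjusted p = 1.65e-05, edgeR). Between the hybrids PIF4 differed by −0.16 (SE 0.11, adjusted p = 1.0, edgeR), lower in the pif4 hybrid in 3 of 4 pairs, and the hybrids' temperature effects differed by 0.15 (SE 0.24). A transcript level does not tell a functional from a mutant copy, and a first-generation hybrid with pif4-101 would also carry the PIF4 copy of C24, so these counts do not check the genotype.

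**Figure D1:**
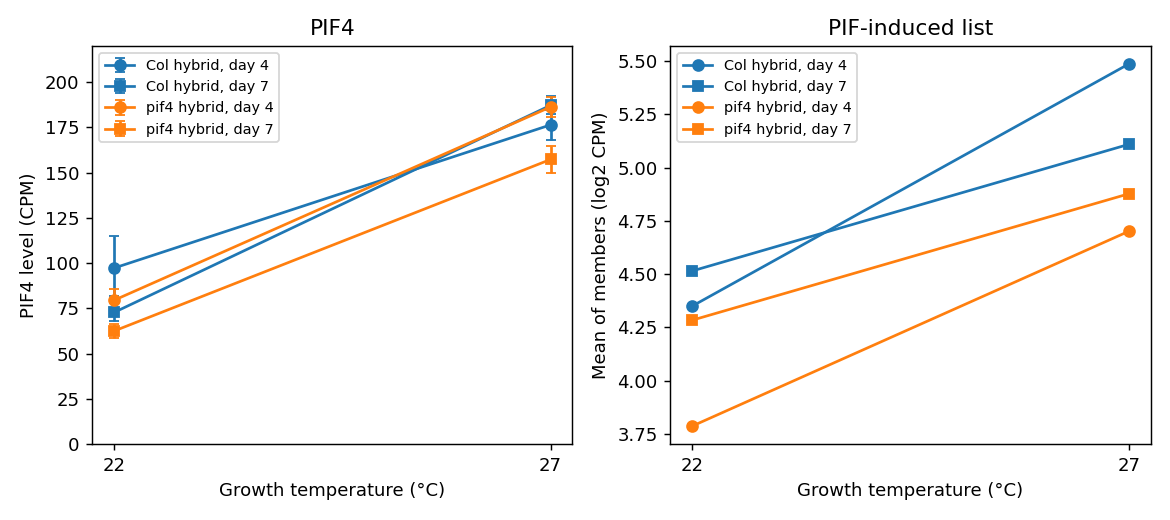
PIF4 level (left, TMM-scaled CPM, with 95% exact binomial intervals for counting error as bars) and the mean level of the 23 PIF-induced genes (right, log2 CPM, no error drawn) against growth temperature; each point is 1 library, and lines join libraries of 1 hybrid and age. PIF4 lay between 62.5 and 97.3 CPM at 22 °C and between 157.3 and 187.2 CPM at 27 °C in both hybrids, and at each temperature and age the mean of the PIF-induced genes was lower in the pif4 hybrid.

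The temperature comparison asks which transcripts differ between seedlings kept at a moderate and a warm temperature. At 27 °C, genes of shade and elongation growth, heat shock, ethylene signalling and sugar starvation were higher, whereas genes of cell division, chlorophyll synthesis and glucosinolate synthesis were lower, as were the single iron uptake genes IRT1 and FRO2. These group calls come from camera with the preset correlation, and 0 of 26 lists passed with an estimated correlation, whereas fry called 15, of which camera with the preset correlation had called 10. Of the lists that camera called with the preset correlation, fry did not call auxin early response or light harvesting (adjusted p = 0.121 for each), and it called the others. Of 19829 genes, 3866 rose and 3810 fell (edgeR, adjusted p under 0.05), and 532 and 546 of these changed at least 2-fold. Of all genes, 47.6% had the same sign in all 4 pairs, against the 12.5% that chance gives. Among the 7676 the share was 83.3%, but these genes were selected by their agreement between the same pairs, which raises it. Without the Col hybrid 22 °C day 7 library the count was 4246, and with the library total as a covariate, an alternative added after seeing the data, it was 4800.

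The steepest rises included HSP17.6A, a small heat shock protein (5.89, SE 0.49), AT2G15880, a leucine-rich repeat protein (4.09, SE 0.33), THA1, a threonine aldolase (3.90, SE 0.44), and ST2A, a sulfotransferase (3.14, SE 0.28). HSP17.6A was read at 14.6 CPM and 36.5 CPM in the 27 °C day 7 libraries of the Col and pif4 hybrids and at most 1.37 CPM in the other six, so its fold rests on day 7. AT5G44440, of the berberine bridge enzyme family, rose by 3.05 (SE 0.49) and RTFL21 by 2.66 (SE 0.28). Genes that fell most included CYP82C4 (−4.32, SE 0.23), a cytochrome P450 of the iron deficiency response, and IRT1 (−3.39, SE 0.19), the main iron transporter of the root epidermis. AT1G29720, a receptor kinase (−4.07, SE 0.26), AT2G15020 (−2.66, SE 0.19), AT5G55570 (−2.63, SE 0.16) and AT1G65870 (−2.57, SE 0.24) also fell. These 12 genes, chosen among those with 1 sign in all pairs, had edgeR adjusted p between 8.19e-07 and 0.000528.

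Among the PIF family, PIF4, PIF3 (1.08, SE 0.17) and PIF6 (0.67, SE 0.15) rose, and PIF7 (−0.53, SE 0.14) and UNE10, also called PIF8 (−1.13, SE 0.12), fell. PIF1 (0.25, adjusted p = 0.0686, edgeR) and PIF5 (0.32, adjusted p = 0.0586) did not pass; adjusted over the list alone, 5 members rose and 2 fell, and the family did not pass camera (adjusted p = 0.275, limma). The PIF7 call was lost without the Col hybrid 22 °C day 7 library (adjusted p = 0.0524) or the pif4 hybrid 27 °C day 7 library (0.0547). Of 23 PIF-induced shade and elongation genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.90. They included CKX5, a cytokinin oxidase (2.36, SE 0.15), XTH15, a wall-modifying enzyme (2.31, SE 0.16), and the homeodomain gene ATHB2 (0.97, SE 0.12). The list passed by camera (adjusted p = 0.000450, limma) and fry (0.0185), but had adjusted p = 0.483 with an estimated correlation.

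Auxin genes moved in part. Of 23 early response genes 9 rose and 2 fell (10 and 2 adjusted over the list alone), among them GH3.5 (1.23, SE 0.11), IAA29 (0.90, SE 0.19) and IAA19 (1.11, SE 0.32) upward and IAA17 (−0.80, SE 0.12) downward. Their camera call (adjusted p = 0.0159, limma) had adjusted p = 0.558 with an estimated correlation and 0.121 by fry. Without the Col hybrid 22 °C day 4 library 5 of them rose, and the camera call was lost without the Col hybrid 27 °C day 4 library (0.305) or the pif4 hybrid 22 °C day 4 library (0.0821). The IAA19 call was lost without any 1 of 4 libraries, at adjusted p from 0.0538 (Col hybrid 22 °C day 4) to 0.0714 (pif4 hybrid 22 °C day 4), with 0.0556 without the Col hybrid 22 °C day 7 library and 0.0541 without the pif4 hybrid 27 °C day 7 library. Of 9 auxin synthesis genes, YUC8, a rate-limiting flavin monooxygenase, rose (0.97, SE 0.20) and CYP79B2 and CYP79B3 fell; the list had a camera adjusted p of 0.272. The median of the auxin synthesis list was −0.27. CYP79B3 lost its call without the Col hybrid 22 °C day 7 library (0.0735), and CYP79B2 without that library (0.122), the pif4 hybrid 22 °C day 4 library (0.0776) or the pif4 hybrid 27 °C day 7 library (0.0517).

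Ethylene and starvation genes rose. Of 13 ethylene genes 9 rose and 1 fell (10 and 2 adjusted over the list alone), among them the receptor gene ERS2 (1.01, SE 0.15) and the F-box gene EBF2 (0.89, SE 0.14); camera gave adjusted p = 0.00399 (limma) and adjusted p = 0.363 with an estimated correlation. Of 10 genes induced by darkness or sugar starvation 8 rose and 0 fell (9 and 0 adjusted over the list alone; 10 of 10 lay above 0), including BCAT2 (2.60, SE 0.27) and DIN4 (0.99, SE 0.11), both of branched-chain amino acid breakdown. Their camera adjusted p was 0.000188 (limma), with adjusted p = 0.363 with an estimated correlation. Of 18 heat shock genes 13 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 1.14, including HSP70 (2.36, SE 0.13) and HSP90.1 (2.48, SE 0.15). Camera gave adjusted p = 1.81e-06 (limma) for heat shock, and adjusted p = 0.363 with an estimated correlation. With counts thinned to the shallowest library, added after seeing the data, 5 of 11 heat shock genes rose.

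Of 27 clock genes 13 rose and 6 fell (14 and 8 adjusted over the list alone), read at lights on. PRR7 (2.16, SE 0.13) and GI (1.51, SE 0.19), which peak later in the day, rose, as did RVE7 (0.93, SE 0.11), whereas the morning gene LHY fell (−0.90, SE 0.13). CCA1 fell by 0.41 (SE 0.12), a call lost without the Col hybrid 22 °C day 4 library (adjusted p = 0.0536, edgeR) or the Col hybrid 22 °C day 7 library (0.0875). The clock list did not pass camera (adjusted p = 0.104, limma) but passed fry (0.00128); with thinned counts 6 of 22 rose. Gibberellin genes did not pass camera either (5 of 16 rose, 0 fell; adjusted p = 0.111; fry 0.0111), and 2 of 12 rose with thinned counts; GAI rose by 0.62 (SE 0.12). In the brassinosteroid list 2 of 11 rose, CPD (0.75, SE 0.12) and DET2 (0.59, SE 0.13), with camera adjusted p = 0.267 and fry 0.0168.

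Cell division genes fell. Of 27 cell cycle genes 21 fell and 0 rose (23 and 0 adjusted over the list alone), with a median of −0.72, including PCNA1 (−1.28, SE 0.18), the replication clamp, and MCM6 (−1.02, SE 0.16) and MCM7 (−0.86, SE 0.13) of the replicative helicase. Camera gave adjusted p = 2.31e-07 (limma), and adjusted p = 0.363 with an estimated correlation. With counts thinned to the shallowest library 8 of 22 cell cycle genes fell, with a median of −0.53. Of 9 stomatal lineage genes 4 fell and 0 rose (5 and 0 adjusted over the list alone), among them BASL (−1.20, SE 0.26) and MUTE (−1.39, SE 0.32). The stomatal call (camera adjusted p = 0.0265, limma; adjusted p = 0.363 with an estimated correlation) was lost without the Col hybrid 22 °C day 7 library (0.0531), and with thinned counts 0 of 4 members fell in edgeR. Of 5 trichome genes 4 fell, led by ETC1 (−1.15, SE 0.25), with a camera adjusted p of 0.0820 and fry 0.0125; with the library total as a covariate 1 fell. The calls of the trichome genes TRY and CPC were lost without the Col hybrid libraries of 22 °C day 7 (0.0629 and 0.103) or 27 °C day 7 (0.0671 and 0.0809), and that of CPC also without any 1 of the pif4 hybrid libraries (0.0635 to 0.160). Of 49 ribosomal protein genes 36 fell and 3 rose (38 and 3 adjusted over the list alone), such as RPL24A (−0.88, SE 0.12), with camera adjusted p = 5.22e-07 and adjusted p = 0.483 with an estimated correlation. With read-density offsets, added after seeing the data, 23 ribosomal genes fell and 4 rose, and with the library total as a covariate 19 fell and 1 rose.

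Chlorophyll and light-harvesting genes were lower at 27 °C. Of 15 chlorophyll synthesis genes 13 fell and 1 rose (the same counts adjusted over the list alone), including CHLI1 of magnesium chelatase (−1.12, SE 0.14), CAO (−0.99, SE 0.13) and PCB2 (−1.06, SE 0.15). Camera gave adjusted p = 9.12e-06 (limma) for chlorophyll synthesis, and adjusted p = 0.363 with an estimated correlation. Of 29 light-harvesting and photosystem genes 15 fell and 0 rose (21 and 0 adjusted over the list alone), with a median of −0.70, such as LHCB4.3 (−0.98, SE 0.21) and RBCS1B (−1.20, SE 0.30). Their camera adjusted p was 9.20e-07 (limma), and adjusted p = 0.558 with an estimated correlation and 0.121 by fry. The median of the list was −1.10 and −0.92 in the Col hybrid on day 4 and day 7 and −0.94 and 0.09 in the pif4 hybrid. In the first 3 of these pairs the 27 °C library was the deeper, by 2.46, 1.12 and 1.23 on the log2 scale, and in the fourth it was the shallower, by −0.69. Over the 8 libraries, the median deviation of the 100 most abundant genes fell with log2 total counts (Pearson r = −0.946, exact permutation p = 0.000174; Spearman rho = −0.929, exact permutation p = 0.00223; 1 relation, two-sided). Without the libraries farthest from the median depth, Col hybrid 22 °C day 4 and Col hybrid 27 °C day 7, Pearson r was −0.872. Light-harvesting genes were not removed from the 100 genes, so the relation need not be independent of that list. Within each temperature, over 4 libraries, the deviation was lower in each deeper library, from 0.84 to −0.14 at 22 °C and from 0.02 to −0.66 at 27 °C. With read-density offsets, added after seeing the data, 9 light-harvesting genes fell and 3 rose, with a median of −0.08, and 10 chlorophyll genes fell and 1 rose, with a median of −0.38. With the library total as a covariate 9 light-harvesting genes fell, with a median of −0.32, and with counts thinned to the shallowest library 13 fell, with a median of −0.69. Only 3 fell without the Col hybrid 22 °C day 4 library.

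**Figure D2:**
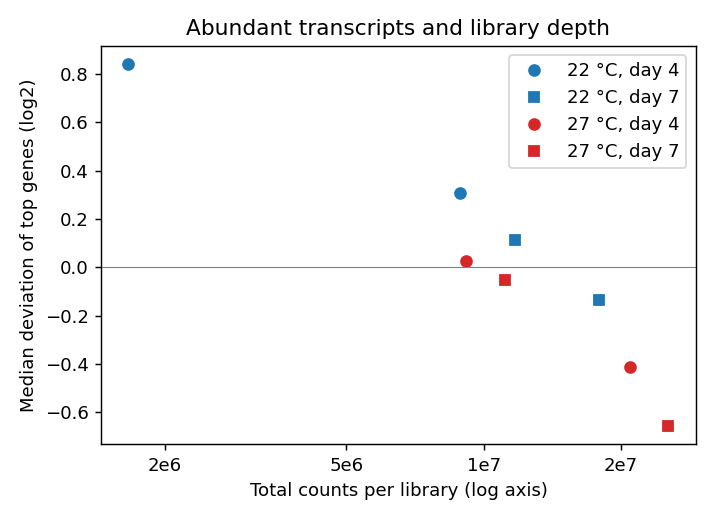
Median deviation of the 100 most abundant genes from their mean over the 8 libraries (log2, vertical axis) against total counts per library (log axis); each point is 1 library, blue for 22 °C and red for 27 °C, circles for day 4 and squares for day 7. The deviation was 0.84 in the shallowest library (1664128 counts) and −0.66 in the deepest (25440561 counts).

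Glucosinolate genes, which make the sulfur-rich defence compounds of the cabbage order, fell with warmth. Of 21 members 14 fell and 2 rose (15 and 2 adjusted over the list alone), including the regulator MYB29 (−1.62, SE 0.20), FMO GS-OX1 (−1.14, SE 0.14) and SOT17 (−0.94, SE 0.13); camera gave adjusted p = 0.000885 (limma), and adjusted p = 0.363 with an estimated correlation. Of 11 flavonoid and anthocyanin genes 7 fell and 1 rose (8 and 1 adjusted over the list alone): DFR (−3.50, SE 0.40) and TT19 (−3.32, SE 0.43) of the late pathway fell, and the repressor MYBL2 rose (0.95, SE 0.12). The flavonoid camera call (adjusted p = 0.0314, limma; adjusted p = 0.363 with an estimated correlation) was lost without any 1 of 5 libraries. Without the Col hybrid day 4 or day 7 library at 22 °C the adjusted p was 0.0634 or 0.261, and without the pif4 hybrid libraries of 22 °C day 4, 22 °C day 7 or 27 °C day 7 it was 0.255, 0.312 or 0.0544. With thinned counts 2 of 4 flavonoid genes fell.

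The other lists did not pass camera. Of 16 root genes 3 fell and 1 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.135, limma), with IRT1 and the ferric reductase gene FRO2 (−2.51, SE 0.15) far below the list's median of −0.16. Cold response genes were mixed (5 rose and 4 fell of 14; camera adjusted p = 0.140; fry 0.0412), with COR413IM1 upward (1.97, SE 0.12). Of 9 abscisic acid genes 4 rose (0.149), among them RD29B (1.74, SE 0.40). Of 14 salicylic acid genes 2 rose and 5 fell (0.422), with WRKY70 upward (0.73, SE 0.13) and ICS1 downward (−0.64, SE 0.12). Of 12 jasmonate genes 1 rose, LOX3 (0.99, SE 0.18), and 2 fell (0.267). Cell wall loosening genes split into 5 that rose and 8 that fell of 24 (camera adjusted p = 0.497), with XTH24 (1.34, SE 0.12) and EXPA16 (1.52, SE 0.19) upward; camera pointed down and fry up. Of 18 flowering genes 2 rose and 2 fell (0.895), SVP (0.53, SE 0.11) upward and SNZ (−0.98, SE 0.11) downward, whereas the floral repressor FLC did not pass (−0.19, SE 0.11, adjusted p = 0.192). Of 7 seed genes MLS (0.63, SE 0.15) and PCK1 (0.49, SE 0.12) rose (camera adjusted p = 0.137), the PCK1 call being lost without the Col hybrid 22 °C day 7 library (0.0699).

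The genotype-by-temperature term asks whether the response to warmth differs between the hybrids, the question posed by the title of the series. The hybrids' responses were alike across genes. The mean log2 ratio of 27 °C to 22 °C in the Col hybrid and in the pif4 hybrid correlated with Pearson r = 0.732 and Spearman rho = 0.742 across 19829 genes, which are not independent replicates. The pairs shared no library. The correlation was 0.419 on day 4 alone, where the shallowest library takes part, 0.830 on day 7 alone and 0.877 among the 13199 genes with a mean of at least 10 CPM. Within the Col hybrid 926 genes rose and 1281 fell, and within the pif4 hybrid 1250 rose and 1368 fell (edgeR). Of these, 650 rose in both and 877 fell in both, where 58.4 and 88.4 would be shared by independent lists. Both lists came from 1 fit with the same spread per gene. They are therefore not independent, and may share more genes than that even without a common response. CYP82C4 fell by 4.43 (SE 0.38) in the Col hybrid and by 4.25 (SE 0.32) in the pif4 hybrid, and IRT1 by 3.55 (SE 0.31) and 3.28 (SE 0.28). AT2G15880 rose by 4.79 (SE 0.52) and 3.67 (SE 0.41), and THA1 by 3.96 (SE 0.68) and 3.84 (SE 0.62). Without the Col hybrid 22 °C day 7 library the Col hybrid calls of CYP82C4 (adjusted p = 0.0525, edgeR), AT2G15880 (0.157) and THA1 (0.301) were lost, and without the pif4 hybrid 27 °C day 4 library the pif4 hybrid call of THA1 (0.0941) was lost.

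For the difference between the hybrids' temperature effects, edgeR called 0 genes, with 188 at an unadjusted p under 0.05. DESeq2 and limma-voom also called 0, with 64 and 210 at an unadjusted p under 0.05. The smallest p belonged to LTP6 (1.19, SE 0.25), ATPMEPCRD (−1.01, SE 0.25) and AT4G38950 (0.81, SE 0.21), none past the threshold (adjusted p = 1.00, edgeR). In simulated data 63.0% of 4-fold and 1.0% of 2-fold differences of this kind were recovered. By camera, the light-harvesting list lay higher in this term (29 of 29 members, median 0.70, adjusted p = 3.42e-09, limma; adjusted p = 0.997 with an estimated correlation), as did chlorophyll synthesis (0.29, 0.00147; adjusted p = 0.875 with an estimated correlation). Cold response lay lower (−0.40, 0.00678; adjusted p = 0.875 with an estimated correlation), and fry called 0 of 26 lists. The light-harvesting call was lost without the Col hybrid 27 °C day 7 library (0.126), and without the pif4 hybrid 27 °C day 7 library the list changed sign and did not pass (0.863). The 27 °C libraries of the Col hybrid were deeper than those at 22 °C at both ages, and that of the pif4 hybrid only on day 4, so that depth is not balanced in this term. Its median in this term was −0.0067 with the library total as a covariate, 0.125 with read-density offsets and 0.73 with thinned counts. The chlorophyll call was lost without the Col hybrid libraries of 22 °C day 7 (0.0711) or 27 °C day 7 (0.205), or the pif4 hybrid libraries of 22 °C day 7 (0.0538) or 27 °C day 7 (0.320). The cold call was lost without the Col hybrid libraries of 27 °C day 4 (0.588) or 22 °C day 7 (0.164), or the pif4 hybrid libraries of 27 °C day 4 (0.114) or 22 °C day 7 (0.220). The counts within a hybrid depended on single libraries: the Col hybrid's count was 5 without its 22 °C day 7 library, 964 without its 22 °C day 4 library, 1322 without its 27 °C day 7 library and 6195 without its 27 °C day 4 library. The pif4 hybrid's count was 620, 90, 244 and 408 without its libraries of 22 °C day 4, 27 °C day 4, 22 °C day 7 and 27 °C day 7, and 6120 and 6110 without the Col hybrid's 27 °C libraries of day 4 and day 7.

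**Figure D3:**
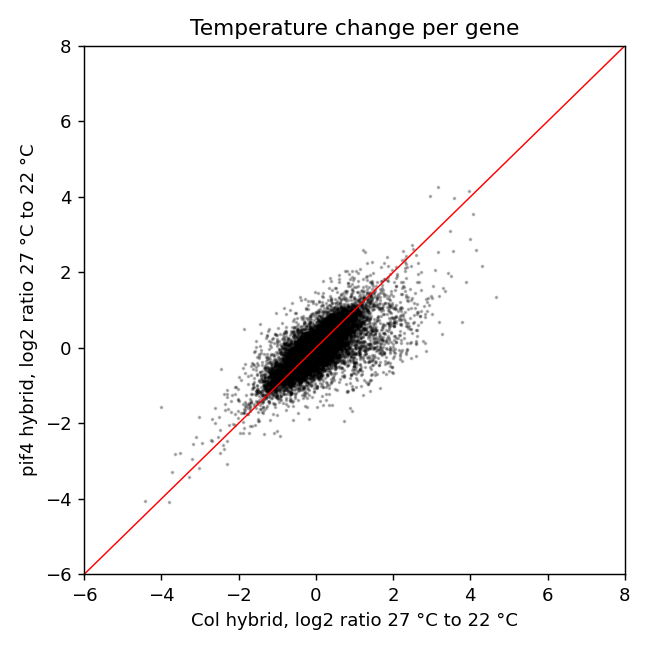
Temperature change per gene in the Col hybrid (horizontal axis) and in the pif4 hybrid (vertical axis), as log2 ratio of 27 °C to 22 °C averaged over day 4 and day 7; each of the 19829 points is a gene, and the red line marks equal change. The points follow the line with Pearson r = 0.732 across genes.

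The genotype comparison asks what differs between the pif4 hybrid and the Col hybrid at all temperatures and ages. PIF-induced growth genes lay lower in the pif4 hybrid as a group by camera with the preset correlation, but not with an estimated correlation or by fry, and no single one passed. XTH15 (−0.95, SE 0.16), ST2A (−1.62, SE 0.27) and PIL1, a shade marker (−0.68, SE 0.13), were lower in 4 of 4 pairs, with adjusted p = 0.139, 0.139 and 0.301 (edgeR). IAA29 (−0.91, SE 0.18), IAA19 (−0.94, SE 0.30) and ATHB2 (−0.42, SE 0.11) were lower in 4 of 4 pairs too, with adjusted p = 0.337, 1.0 and 0.677. Of 23 PIF-induced genes 21 lay below 0 with a median of −0.43, and 0 passed over all genes but 11 fell adjusted over the list alone. In single pairs 19 of 23 were lower at 22 °C and 22 of 23 at 27 °C on day 4 (medians −0.41 and −0.70), and 20 and 16 of 23 on day 7 (medians −0.11 and −0.24). Camera gave adjusted p = 2.55e-12 (limma), whereas adjusted p = 0.414 with an estimated correlation and 0.283 by fry; the preset call held without each single library.

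In the genotype comparison edgeR called 1 gene of 19829, AT5G35935, an uncharacterised protein gene higher in the pif4 hybrid in 4 of 4 pairs (1.73, SE 0.19, adjusted p = 0.0122); 795 genes had an unadjusted p under 0.05. DESeq2 called 11, limma-voom 1 and edgeR without a filter 15. With all pairwise interactions in the model the count was 146. On day 4 alone 26 genes were higher and 195 lower in the pif4 hybrid, and on day 7 alone 328 were higher and 137 lower; whether these effects differ between the ages was tested by the genotype-by-age term. Of all genes 13.6% had the same sign in all 4 pairs, near the 12.5% of chance. The AT5G35935 call was lost without the Col hybrid 22 °C day 7 library (adjusted p = 0.0612), or the pif4 hybrid libraries of 22 °C day 4 (0.0522), 27 °C day 4 (0.137) or 27 °C day 7 (0.247). The count of genes was 13, 2 and 12 without the Col hybrid libraries of 27 °C day 4, 22 °C day 7 and 27 °C day 7, 8 without the pif4 hybrid 22 °C day 7 library, and 0 without each of the other three pif4 hybrid libraries.

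By camera with the preset correlation, 13 lists passed in the genotype comparison, 11 lower and 2 higher in the pif4 hybrid, but 0 of 26 passed with an estimated correlation or by fry. Lower were gibberellin (median −0.18, adjusted p = 0.000165; adjusted p = 0.297 with an estimated correlation) and starvation genes (−0.31, 0.000165; adjusted p = 0.414 with an estimated correlation), and higher were glucosinolate genes (0.19, 0.000110; adjusted p = 0.414 with an estimated correlation). These calls held without each single library. Auxin early response genes (−0.17, 5.54e-05; adjusted p = 0.558 with an estimated correlation), ethylene genes (0.00241; 0.313), cold genes (0.000726; 0.414), abscisic acid genes (0.0370; 0.653) and cell wall genes (0.000872; 0.424) were lower, each pair of values being the preset and the estimated adjusted p. So were seed genes (0.00507; 0.414), root genes (0.00527; 0.653) and light-harvesting genes (0.000165; 0.705), and flowering genes were higher (0.0145; 0.414). The median of the light-harvesting genes was −0.75 at 22 °C and −0.57 at 27 °C on day 4, and −0.31 and 0.72 on day 7, so that 0 of 29 members were lower in all 4 pairs. The pif4 hybrid library was the deeper in the first 3 of these pairs, by 2.42, 1.19 and 0.61 on the log2 scale, and the shallower in the fourth, by −1.19, so that this call cannot be separated from depth. With the library total as a covariate the median of the list was 0.07 between the hybrids, with read-density offsets −0.05 and with thinned counts −0.21, against −0.20 without them. Without the Col hybrid 27 °C day 4 library the calls of auxin (0.408), ethylene (0.0615), cold (0.396), abscisic acid (0.830), cell wall (0.330) and seed genes (0.408) were lost. The light-harvesting call was lost without the Col hybrid 22 °C day 4 library (0.666) or the pif4 hybrid 27 °C day 4 library (0.279), and the flowering call without the Col hybrid (0.297) or pif4 hybrid (0.162) library of 22 °C day 7. The root call was lost without the Col hybrid libraries of 22 °C day 4 (0.307) or 27 °C day 7 (0.147), or the pif4 hybrid libraries of 27 °C day 4 (0.151) or 22 °C day 7 (0.0882). The ethylene call was also lost without the Col hybrid 27 °C day 7 library (0.0773). The abscisic acid and seed calls were also lost without the Col hybrid 22 °C day 7 library (0.382 and 0.0595) or the pif4 hybrid libraries of 22 °C day 4 (0.439 and 0.114) or 27 °C day 7 (0.244 and 0.0603). The iron uptake genes IRT1 (0.97, SE 0.19, adjusted p = 0.301, edgeR) and FRO2 (0.63, SE 0.15, adjusted p = 0.524) did not pass.

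The age comparison asks which transcripts differ between day 4 and day 7. On day 7 glucosinolate genes were higher and root genes were lower, and the single genes that fell most included 4 extensin genes, whose reads can be shared between paralogs. The group calls come from camera with the preset correlation, and 0 of 26 lists passed with an estimated correlation, whereas fry called 6, of which camera with the preset correlation had called 3. Of 19829 genes 4913 rose and 4758 fell (edgeR), 940 and 614 of them at least 2-fold. The same sign in all 4 pairs was seen for 55.4% of all genes and for 90.3% of the 9671, a share raised by their selection. The steepest rises included AOP2 (4.50, SE 0.24), GSTF11 (4.24, SE 0.19), BCAT4 (4.06, SE 0.24), FMO GS-OX3 (4.02, SE 0.20) and AK3 (3.84, SE 0.13). AOP2, BCAT4 and FMO GS-OX3 act in aliphatic glucosinolate synthesis. The steepest falls were in the extensin genes EXT12 (−4.56, SE 0.35), EXT13 (−4.45, SE 0.31), EXT6 (−3.56, SE 0.35) and EXT10 (−3.40, SE 0.39), which encode wall proteins, in the nitrate transporter gene NRT1.8 (−3.49, SE 0.43) and in AT1G19900 (−3.26, SE 0.24).

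Of 21 glucosinolate genes 18 rose and 1 fell with age (19 and 1 adjusted over the list alone), with a median of 1.02, including CYP79F1 (3.59, SE 0.16), CYP83A1 (2.92, SE 0.12) and MAM1 (2.59, SE 0.12). Camera gave adjusted p = 2.57e-09 (limma), and adjusted p = 0.768 with an estimated correlation; fry gave 0.000539. Of 16 root genes 11 fell and 0 rose (12 and 0 adjusted over the list alone), such as the auxin carrier gene PIN2 (−1.07, SE 0.10), CASP5 of the Casparian strip (−1.66, SE 0.19) and TIP2;3 (−1.12, SE 0.13). Camera gave adjusted p = 0.000245 (limma) for root genes, and adjusted p = 0.853 with an estimated correlation. Of 49 ribosomal protein genes 33 rose and 2 fell (36 and 2 adjusted over the list alone), such as RPS18C (0.95, SE 0.14), with camera adjusted p = 4.50e-05, adjusted p = 0.853 with an estimated correlation and 0.0535 by fry. With thinned counts 7 of 11 root genes fell.

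Of 10 starvation genes 8 fell, including TPS9 (−0.85, SE 0.13), with camera adjusted p = 0.0378 (limma), adjusted p = 0.853 with an estimated correlation and 0.0776 by fry. With the library total as a covariate 3 fell, and without the Col hybrid 22 °C day 4 library 4 fell. This call was lost without the Col hybrid libraries of 22 °C day 4 (0.081), 27 °C day 4 (0.0595) or 22 °C day 7 (0.0545). Of the PIF family 4 of 7 fell with age, among them UNE10 (−0.85, SE 0.12), PIF3 (−0.69, SE 0.16) and PIF1 (−0.44, SE 0.10), with camera adjusted p = 0.0313 and adjusted p = 0.853 with an estimated correlation; the call was lost without the Col hybrid 22 °C day 4 library (0.081). With the library total as a covariate the median of the light-harvesting genes was −0.03 for age, against −0.45 without it. Light-harvesting genes had a camera adjusted p of 0.00702 (5 fell of 29, 1 adjusted over the list alone; adjusted p = 0.853 with an estimated correlation; fry 0.358), a call lost without the Col hybrid libraries of 22 °C day 4 (0.101), 27 °C day 4 (0.0613) or 27 °C day 7 (0.116). Of the light-harvesting genes 14 fell and 3 rose with read-density offsets, 2 fell with the library total as a covariate and 1 fell without the Col hybrid 22 °C day 4 library. Ethylene genes did not pass camera (0.0501), although 9 of 13 fell and fry gave 0.000539. Other genes that rose with age were the floral regulators AGL24 (2.33, SE 0.33) and SVP (1.05, SE 0.11), LOX2 of jasmonate synthesis (2.14, SE 0.21), the cold gene KIN2 (2.19, SE 0.19) and the stomatal peptide gene EPFL9 (1.15, SE 0.13). The seed regulator ABI3 (−2.97, SE 0.46) and the gibberellin synthesis gene GA3OX1 (−1.28, SE 0.16) fell.

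The age-by-temperature term asks whether warmth acts differently on day 4 and day 7. Where seedlings of both ages were moved to 27 °C at the same time, those of day 7 had spent longer in warmth. Age and length of warmth then cannot be told apart in this term, or in the age pairs at 27 °C. Gene lists were not tested for this term. Some late embryogenesis genes were higher at 27 °C on day 4 and lower on day 7 in both hybrids, and the wall protein genes EXT6, EXT10 and HRGP1 did the reverse. The root list's median temperature change was −0.53 and −0.46 on day 4 in the Col and pif4 hybrids, and 0.09 and 0.31 on day 7. Whether these changes share a cause was not tested. In edgeR 53 genes passed, 38 with a lower and 15 with a higher temperature effect on day 7. Among genes with a mean of at least 5 CPM, the lowest terms were those of AT3G17520 (−7.69, SE 0.92), LEA18 (−6.89, SE 0.78) and LEA7 (−6.55, SE 0.89), late embryogenesis abundant proteins or their relatives, and PER1, a seed peroxiredoxin (−6.38, SE 1.15). In the Col hybrid LEA7 was at 5.01 CPM at 22 °C and 33.7 CPM at 27 °C on day 4, and at 3.24 CPM and 0.423 CPM on day 7. The highest were EXT10 (2.55, SE 0.47), AT5G03545 (2.47, SE 0.31), EXT6 (2.27, SE 0.43) and HRGP1 (2.18, SE 0.40). Many of these genes were near the floor in the shallowest library, where PER1 had 0 counts, so that its fitted term is no bound. The calls of all 8 genes were lost without the Col hybrid 22 °C day 4 library (adjusted p from 0.0775 to 0.341, edgeR), and those of 7, all but HRGP1, without the pif4 hybrid 22 °C day 4 library (0.137 to 0.647). Without the Col hybrid 22 °C day 7 library EXT10 (0.118), EXT6 (0.218) and HRGP1 (0.167) were lost, without the Col hybrid 27 °C day 7 library EXT6 (0.109), and without the pif4 hybrid 22 °C day 7 library EXT10 (0.304), EXT6 (0.219), HRGP1 (0.0989) and PER1 (0.173). The count was 0 without the Col hybrid 22 °C day 4 library, 1 without the pif4 hybrid 22 °C day 4 library and 1780 without the pif4 hybrid 27 °C day 4 library. It was 119, 28, 91, 16 and 121 without the libraries of Col hybrid 27 °C day 4, 22 °C day 7 and 27 °C day 7 and of pif4 hybrid 22 °C day 7 and 27 °C day 7.

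The genotype-by-age term asks whether the hybrids differ in how transcripts change with age. In edgeR 18 genes passed, each lower in both day 7 libraries of the Col hybrid than in any of the other six, SEC61 BETA least so, at 18.5 CPM and 4.73 CPM against 37.9 to 81.4 CPM. PRP39-2 (5.27, SE 0.36), LRR XI-23 (5.23, SE 0.26), ATMAP4K ALPHA1 (5.13, SE 0.26) and SYCO ARATH (4.70, SE 0.34) had the highest terms. LRR XI-23, a receptor kinase gene, was at 123.1 CPM and 146.7 CPM in the Col hybrid on day 4 but at 2.19 CPM and 1.80 CPM on day 7, and at 67.0 CPM and 98.3 CPM in the pif4 hybrid on day 7. Others encode enzymes of plastids, such as PDH-E1 ALPHA and PDH-E1 BETA of pyruvate dehydrogenase and KAS III of fatty acid synthesis. Over the 18 genes, the mean level in these libraries was 1.55% to 18.6% of that in the other six, with a median of 4.80%. Of the 18 genes, 15 have a space in their reference name, so that a step in the making of the counts may lie behind their terms. Such a step would set both Col hybrid day 7 libraries apart from the others. Whether it also touched other genes in this term, or in the genotype comparison on day 7, was not tested. The count was 35 without the Col hybrid 22 °C day 4 library and 74 without the pif4 hybrid 22 °C day 7 library.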

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

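The tests of seed transcripts, of gene names with a space and of other splits of the libraries were chosen only after the results were seen, whereas the test of overlap with a neighbouring gene was chosen before.

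The age-by-temperature term passed for 53 genes, a difference in the effect of warmth between the ages or between the lengths of warmth. Among them PER1, LEA7 and ICL were higher at 27 °C on day 4 and lower on day 7 in the Col hybrid. In contrast, ICL in the pif4 hybrid, and MLS and PCK1 of the seed list in both hybrids, were higher at 27 °C at both ages. A shallow Col hybrid 22 °C day 4 library is argued against as the whole cause, since the median of the seed list also rose by 1.37 (log2) in the pif4 hybrid day 4 pair, which lacks that library. Pools with different shares of seed tissue may be behind it, but ratios of the Col to the pif4 hybrid at 27 °C on day 4 ran from −0.20 for ABI3 to 2.49 for EM6 with an SD of 0.994, between the bounds of 0.5 and 1 that were to decide it. As first written, the test would have counted ABI3 as an opposite sign, which was wrong because its 95% counting interval, −0.66 to 0.27, includes 0. A later loss of seed transcripts at 1 of the temperatures, which the design names through age and temperature, stays open and untested.

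For the count of 53 the splits alone do not exclude chance, because 4 of 32 splits of the 8 libraries called as many genes, the highest other split calling 1067. That split exchanges the Col hybrid 27 °C libraries of both ages in the age comparison and calls many times the real count, which points to a structure of the samples. Across genes, the change with age in the Col hybrid at 27 °C had a slope of 0.498 on the mean of the other pairs. The slopes of the other pairs ran from 0.827 to 1.1.

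The genotype-by-age term passed for 18 genes, a difference between the hybrids in the effect of age, and each of them, such as LRR XI-23 and KAS III, was lower in both Col hybrid day 7 libraries than in any other, at 1.55% to 18.6% of their mean. Of the 18, 15 have a gene name with a space, against 38 of the other tested genes (Fisher's exact test, two-sided, p = 2.31e-37), which is consistent with a step in the making of the counts that split names at spaces. A loss of every such gene is argued against only as far as the term could call it. Of the 53 tested genes with such a name 28.3% were among the 18. In simulated data 66.0% of 4-fold differences of this kind were recovered, so a gene short of the threshold is not shown to be kept. PRP39-2, CST and TRANS11 were among the 18 without a space in their reference symbol. Overlap with a neighbouring gene was about as common among the 18 genes (33.3%) as among the others (31.3%; Fisher's exact test, two-sided, p = 0.805), and 18 genes are too few to decide on it. For the 15 genes with a space, this share of names argues against a biological difference between the hybrids on day 7, which would not track spelling. For PRP39-2, CST and TRANS11 such a difference stays open and untested. Only the reference symbol was searched for a space, and another of their names may hold one. The splits alone do not exclude chance, as 5 of 32 called as many genes. The highest other called 1067, and 1 of them was the age-by-temperature term (53). The splits do not account for the names with a space.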

How the results depend on the processing

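The library total as a covariate, the read-density offsets, the thinning of counts and the ribosomal list limited by text were chosen only after the data were seen.

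Scaling by RLE or upper quartile and leaving out organelle genes kept every count of genes within 1.5 times its value. The genotype-by-temperature count was 0 under all alternatives run. Of the values of named genes under the alternatives, 6365 kept their direction and side of the threshold, 300 fell short of it, 94 came to pass it, 74 changed sign without a call on either side and 0 with one. Of those of lists, 1007, 100, 46, 86 and 9 did so.

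The 9 reversals of lists came with 1 library left out. In the genotype by temperature gene lists, light harvesting and photosystems, called higher on all libraries, turned lower without the pif4 hybrid 27 °C day 7 library (adjusted p = 0.863; 1.26e-50 to 0.863 over the libraries). The other 8 were not called on all libraries and passed in the opposite direction. In that term these were cell cycle without the Col hybrid 22 °C day 4 library (0.0296; range 0.0296 to 0.982) and PIF-induced shade and elongation genes without the Col hybrid 27 °C day 4 library (0.0283; range 0.00311 to 0.922). Auxin early response did so without the Col hybrid 27 °C day 7 (0.0106) or pif4 hybrid 22 °C day 4 library (0.0289; range 1.5e-06 to 0.921), and cytosolic ribosomal proteins without the Col hybrid (1.5e-06) or pif4 hybrid 27 °C day 4 library (0.0115; range 1.5e-06 to 0.982). In the genotype gene lists cytosolic ribosomal proteins did so without the Col hybrid (0.0288) or pif4 hybrid 27 °C day 4 library (0.0482; range 0.00132 to 0.944).

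The count of temperature genes was 1909 with no covariates, 1078 with a 2-fold minimum, 2934 on day 4 alone (10087 on day 7 alone), 1752 in the Col hybrid alone (6487 in the pif4 hybrid alone), 4800 with the library total as a covariate and 3856 with thinned counts. Without 1 library it ran from 4246 to 9827. Day genes numbered 5483 with no covariates, 1554 with a 2-fold minimum and 5821 with thinned counts. Genotype genes numbered 15 with no filter, 11 by DESeq2, 146 with all pairwise interactions, 221 on day 4 alone, 465 on day 7 alone and 9 with thinned counts. Genotype genes numbered 0 by edgeR with no covariates (40 at an unadjusted p under 0.05) and 0 with the library total as a covariate (551), and 0 to 13 without 1 library, where limma-voom on all libraries called 1.

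The day by temperature genes numbered 294 with no filter, 15 with a mean of at least 5 CPM, 22 by limma-voom, 84 with read-density offsets and 7 with thinned counts, and 0 to 1780 without 1 library. The genotype by day genes numbered 15 to 74 without 1 library. Temperature genes in the Col hybrid numbered 1241 with thinned counts and 5 to 6195 without 1 library, and temperature genes in the pif4 hybrid 1093 and 90 to 6120.

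With an estimated correlation camera called 0 of 26 lists for temperature, genotype, day and genotype by temperature, and fry called 0 for genotype and genotype by temperature. Without 1 library camera called 8 to 14 lists for genotype, 3 to 8 for day and 2 to 9 for genotype by temperature. The correlation between the hybrids' temperature effects was 0.419 on day 4 alone, 0.830 on day 7 alone and 0.877 with a mean of at least 10 CPM. Fewer libraries or counts lower the power of a test by construction; for the other changes the cause was not tested. Depth limits genes near 2.14 TMM-scaled CPM in the shallowest library.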

Other observations

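The tests of the light-harvesting list and of other splits of the libraries, and the comparison with random lists, were chosen only after the results were seen.

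All 29 light-harvesting and photosystem genes were lower at 27 °C in 3 of 4 pairs, and 10 of them, among these LHCB4.3 and RBCS1B, were lower in the pif4 hybrid day 7 pair too. Loss of the most abundant transcripts with library depth may be behind part of it: in the pif4 hybrid day 7 pair, where the 27 °C library was the shallower, the list differed from genes of like read density by −0.0262, and with read-density offsets its median was −0.08. Against depth as the whole cause stand gaps of −0.474, −0.279 and −0.349 in the other pairs, although the matched genes were less dense by 0.622 (log2), and a median of −0.32 with the library total as a covariate; thinning, which leaves the composition of a library as it is, left −0.69. A temperature change common to both hybrids and ages cannot be told apart from an effect of depth. The list's median of 0.0876 in the pif4 hybrid day 7 pair was first set as a bound against such a change. However, it comes from the pair in which depth would mask a fall. A temperature effect limited to some ages or hybrids stays open.

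PIF-induced genes had a median of −0.43 between the hybrids, and 0 of 10000 random lists of genes of like level had one as low, the lowest being −0.12. Random lists do not keep the correlation between PIF-induced genes such as XTH15 and IAA29. The effect of genotype at 22 °C and at 27 °C correlated across genes with Pearson r = 0.173, and the effect of temperature on day 4 and day 7 with 0.563; genes are not independent replicates.

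For temperature genes 1 of 35 splits of the libraries called as many, the real one (7676), and the highest other, the split by age, called 4506. For age, 1 of 35 splits called as many as 9671, and the highest other, the split by temperature, called 1083. Each other split left the effect of the tested factor in its spread, in whole or in part, which lowers its calls. The real split was thus favoured, and the splits cannot exclude chance for temperature or age. For genotype genes 10 of 35 splits called at least 1 gene, the highest other being the split by age with 9872, so chance is not excluded. For the genotype-by-temperature term, with 0 genes, 32 of 32 splits called as many by construction, which says nothing about chance; the highest, 1067, points to a structure of the samples. Splits by age and temperature follow the design's own factors.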
